A study of Homo sapiens with 4 samples.

How the data were processed

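Chromatin of CAL-1 cells, a human line from a plasmacytoid dendritic cell (pDC) neoplasm, was immunoprecipitated either with a monoclonal antibody against E2-2 (the helix-loop-helix transcription factor encoded by TCF4) or with mouse immunoglobulin (Ig) as control, per the labels. Both kinds of immunoprecipitate were hybridised against input DNA to a promoter tiling set that is split over 2 array designs, here called chip 1 and chip 2 as in the labels. The 4 arrays are therefore 1 E2-2 array and 1 Ig array per design. The probes of the 2 designs differ, so every probe was measured on 1 array per antibody and there are no replicates. No p-value is given for any gene, region or list, and no difference between the antibodies can be set against a spread between replicates. All 4 arrays were scanned on the same day and each lay on its own slide, so antibody and array cannot be told apart.

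The deposited scanner files hold spot intensities in 2 channels, with the immunoprecipitate in Cy5 and the input in Cy3, per the labels. Per the file headers, the authors extracted the images with Agilent Feature Extraction 9.5.3.1 under a ChIP protocol, with spatial and multiplicative detrending, background subtraction, surrogate values for dim spots and linear dye normalization but no lowess correction. The processed intensity is in arbitrary linear units. The files also give a log10 ratio of red over green per spot and the p-value that the scanner software's error model attaches to it, per the file headers. That p-value concerns 1 spot on 1 array, so it was not used. The authors' deposited value tables hold log2 ratios. They equal the log10 ratio of the scanner files converted to base 2, to within 0.005, in the same direction and without centring. Their medians are -0.34 for E2-2 and -0.50 for Ig on chip 1, and -0.16 for each antibody on chip 2. Which genome build the probe coordinates use is not given in the sources used here, and coordinates, distances to start sites and positions relative to genes are those of the scanner files.

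The main value was the log2 ratio of the processed Cy5 over the processed Cy3 signal, centred on the array's median over non-control probes. Spots flagged in either channel of either array as non-uniform, as population outliers or as not found were left out. This removed 1.34% of the 237210 probes of chip 1 and 1.36% of the 237201 probes of chip 2. Probes without a position, 12 and 7 on these designs, were also left out. E2-2 over Ig is the difference between the centred log2 ratios of the 2 arrays of a design. At each probe, all probes within 500 bp on either side were averaged when there were at least 3. A window was called E2-2-enriched when its mean E2-2 over Ig was at least 1 and its mean E2-2 over input was at least 1, that is 2-fold for both. The background was the mirror call, with the antibodies exchanged. Called windows with centres within 1000 bp of each other were merged into regions. The distance of a window to a start site is that of the probe it is centred on, and its other probes can lie on the other side of the start. A gene's value is its highest window, and a gene was called when it had at least 1 called window. The highest of many windows is above 0 by selection, so lists were set against other genes with a like number of windows. Single genes were not: the share of all genes with a window as high is not matched on number of windows. The SD printed with a window is over its probes and does not measure error between experiments.

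The scanner files name genes by accession and symbol. Of 17762 names, 16358 were brought up to date through a RefSeq accession in a table for GRCh38.p14 that was used for names only. Another 359 were already current, 520 matched a single older synonym and 525 were kept as the files give them. The 12 gene lists were fixed before the data were examined: pDC genes, the Toll-like receptor (TLR) and interferon induction pathway, interferon-stimulated genes, conventional dendritic cell and myeloid genes, B cell genes, T and NK cell genes, helix-loop-helix factors and Id proteins, haematopoietic transcription factors, cell cycle genes, cytosolic ribosomal proteins, genes of liver, muscle, pancreas and neurons, and olfactory receptors. For each list the median of its genes' highest windows was ranked among 10000 random lists of the same size, matched in 5 classes of window number by 5 classes of input signal. The percentile describes these arrays and is not a test between conditions. A list was said to stand apart when it lay outside the central 95% of the random lists. The number of members expected to be called was taken from the share of called genes in the same classes, with the central 95% of random draws.

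The genes named in the text were chosen by a rule fixed before the data were examined. They are the genes of the 12 regions with the highest E2-2 over Ig, 12 genes of interest whether called or not (TCF4, SPIB, IRF7, IRF8, TLR7, TLR9, LILRA4, CLEC4C, PTCRA, BCL11A, ID2 and PACSIN1), up to 15 called members of the pDC list and up to 4 of each other list with the highest windows, and the genes of the 3 mirror regions with the lowest windows. Some genes that this rule names are not reported here.

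Signal over background limits precision. The input was well above background at 97.4% to 99.66% of probes, whereas the immunoprecipitates were so at 86.68% and 87.42% (E2-2) and at 79.99% and 79.9% (Ig) on chips 1 and 2. Replicated control spots had a median SD of the log2 ratio between 0.12 and 0.23 per array. The number of arrays, 1 per antibody and probe, also limits precision.

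The calling and ranking steps were tested on simulated data built from the real probe positions of 17428 genes. The Ig log ratios of each design were shifted along the probes to stand for an unrelated second array. This unrelated pair gave 9818 regions in one direction and 10530 in the other, and 43.6% of genes were called. In the simulated E2-2 against Ig comparison, 200 genes each were raised at 1 place by 2-, 4-, 8- or 16-fold. The median rise of the raised window was 1.00, 2.00, 3.00 and 4.00 on the log2 scale. The construction fixes these values, so they check the arithmetic only. The raised window was called in 33.5%, 71.0%, 91.5% and 96.5% of genes. Lists of 60 such genes ranked at percentiles 97.21, 99.99, 100.0 and 100.0. Of 200 lists of unraised genes, 9 fell outside the central 95%. The unraised lists were drawn at random from the same genes as the lists they were ranked among. Their share outside was thus largely fixed by the construction and checks the ranking arithmetic only.

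Alternatives were thresholds of 1.5-fold and 3-fold, windows of 300 bp on either side, at least 5 probes, the median over probes, normexp background correction with an offset of 50 and loess within arrays (limma 3.58.1 in R 4.3.3), the deposited value table, scaling both arrays of a design to one spread, only probes well above background, E2-2 over input alone, and each design alone. A correction for GC content and a search for E-box motifs, the sequences that helix-loop-helix factors bind, were not run because no probe sequence or genome was used here. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.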

Results

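Binding of E2-2, a helix-loop-helix transcription factor required for plasmacytoid dendritic cells (pDCs), the blood cells that specialise in type I interferon secretion, was measured by chromatin immunoprecipitation and promoter arrays in CAL-1 cells. The 4 arrays were 1 with the E2-2 antibody and 1 with control mouse Ig on each of 2 array designs, each against input DNA. The designs carried 237210 and 237201 probes at a median spacing of about 173 bp on chip 1, and 419311 windows near 17428 genes could be measured. There were no replicates, so no value below has a replicate error, and each ± is the SD over the probes of 1 window. Across probes, which are not independent replicates, the E2-2 and Ig log ratios had a Pearson correlation of 0.325 on chip 1 and 0.256 on chip 2. The log2 input signals of the same arrays had 0.940 and 0.889. Signals and ratios are unlike measures, so the input values are no yardstick for the ratios.

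The comparison of E2-2 with Ig asks which promoters carry E2-2 in a pDC line. Genes characteristic of pDCs stood apart. Of 62 measured pDC genes, 45 had an E2-2-enriched window, against 33.2 expected for genes with a like number of windows and like input signal (central 95% of random draws, 26 to 40). Their median highest window was 2.35 on the log2 scale, E2-2 over Ig, against 1.592 for matched random lists, which placed the list at percentile 99.98. With normexp correction these medians were 1.333 and 0.843, and with loess 1.631 and 1.146. In the mirror comparison, Ig over E2-2, 21 of them were called against 23.6 expected and the list lay at percentile 1.08. B cell genes (0.94) and helix-loop-helix genes (1.2) were as low in that comparison, cell cycle genes (70.11) and ribosomal protein genes (86.77) were not, and olfactory receptors lay at 100. With E2-2 over input alone, without the Ig array, 60 of the 62 genes had a window at or above 2-fold against 46.7 expected (40 to 53). Ig over input gave 34 against 38.9 (32 to 46), at percentile 20.20. In E2-2 over input, ribosomal protein genes (42 of 50, range 27 to 39), cell cycle genes (34 of 38, 23 to 33) and helix-loop-helix genes (26 of 27, 17 to 25) also lay above their ranges. No other list did.

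**Figure D1:**
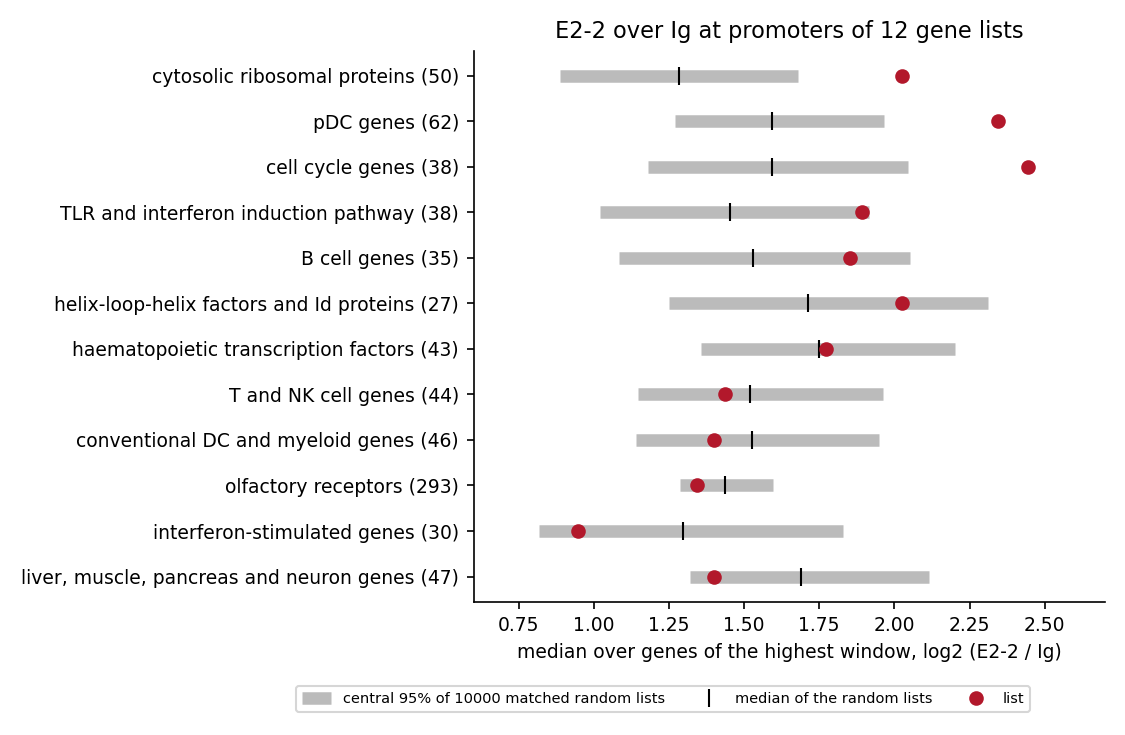
Median over genes of the highest window (log2 of E2-2 over Ig) for 12 gene lists, with the number of measured genes in brackets. Red points are the lists, black ticks the medians of 10000 matched random lists and grey bars their central 95%. The pDC list (2.35), cell cycle list (2.44) and ribosomal protein list (2.02) lie to the right of their bars.

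Among pDC genes, DNASE1L3, which encodes a secreted DNase, had the highest window of all genes, at 7.03 ± 1.51 over 3 probes upstream of its start site (chromosome 3, 58175447 to 58175706). E2-2 over input was 4.98 and Ig over input was -2.05 there, so that part of the difference came from a low Ig ratio. When at least 5 probes were required, that window was not measured and the gene's highest window was -0.54. TLR9, the endosomal receptor for unmethylated CpG DNA, reached 4.37 ± 1.15 over 4 probes, in a window centred on the probe 143 bp upstream of its start, with the other 3 downstream (chromosome 3, 52234928 to 52235386). Its E2-2 over input was 4.38 and its Ig over input 0.01. PACSIN1, a membrane-trafficking adaptor used by pDCs in interferon production, reached 5.11 ± 2.26 over 4 probes inside the gene, centred 941 bp from its start (chromosome 6, 34542436 to 34542850). BCL11A, a zinc finger transcription factor needed for pDC development, had 3.93 ± 0.75 over 5 probes centred 2035 bp upstream (chromosome 2, 60635682 to 60636551). PLD4, a phospholipase D family exonuclease, had 3.83 ± 0.49 over 3 probes, in a window centred on the probe 118 bp upstream, with the other 2 downstream (chromosome 14, 104462091 to 104462517). DNASE1L3, PACSIN1 and BCL11A also held an Ig-enriched window, with lowest windows of -1.49, -2.32 and -2.96, whereas TLR9 and PLD4 held none.

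CLEC4C, which encodes the pDC lectin BDCA-2, had 4.07 ± 1.24 over 3 probes centred 866 bp inside the gene (chromosome 12, 7792441 to 7792842), but was not called when only probes well above background were used (1.31). LILRA4, the pDC receptor ILT7, had 3.62 ± 2.73 over 3 probes centred 4932 bp upstream, a mean that varied widely between probes. PTCRA, the pre-T cell receptor alpha chain that pDCs also express, had 2.68 ± 0.86 over 4 probes centred 4876 bp upstream, but 18.43% of all genes had a window as high. Other called pDC genes with high windows were MAPKAPK2 (5.02 ± 2.39), SERPINF1 (4.93 ± 1.63), PTPRS (4.50 ± 1.23), PLAC8 (4.25 ± 2.44), UNC93B1 (3.92 ± 0.79), HERPUD1 (3.77 ± 1.06), UGCG (3.42 ± 1.45) and JCHAIN (3.37 ± 2.62). Of these only JCHAIN also held an Ig-enriched window, and its lowest window was -3.84. The UNC93B1 window, centred 5089 bp upstream in a promoter the files describe as divergent, was shared with ALDH3B1. The MAPKAPK2 window was centred 4918 bp upstream. The PTPRS window was centred 52547 bp inside the gene, far from the start site given for it. SERPINF1 and UGCG were not called with at least 5 probes (1.15 and 0.95), nor was SERPINF1 with probes well above background (0.93).

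**Figure D2:**
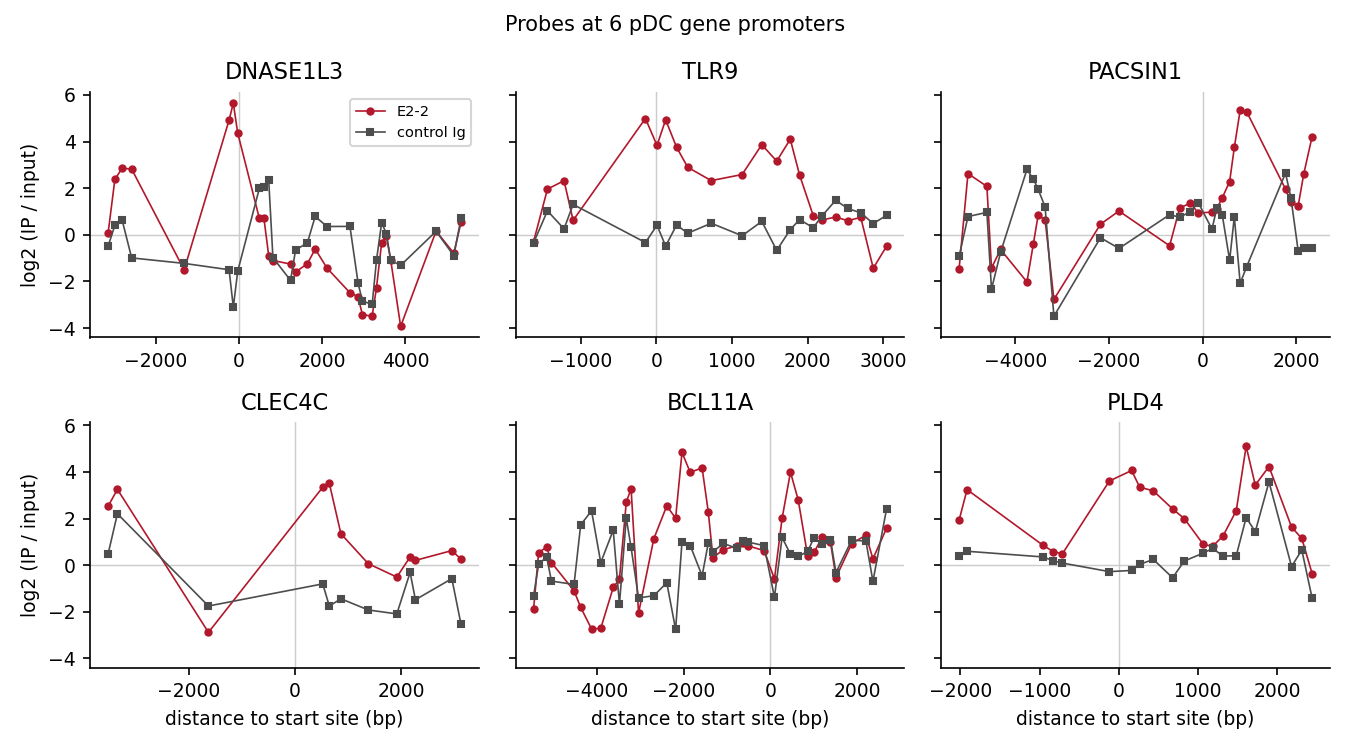
Log2 ratio of immunoprecipitate over input at single probes (points) against distance to the start site in bp, at 6 pDC genes, for E2-2 (red) and control Ig (grey). At TLR9 and PLD4 the E2-2 signal lies above the Ig signal at several adjacent probes around the start, and at DNASE1L3 the peak rests on 3 probes.

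Of the other transcription factors of interest, SPIB had 2.66 ± 0.56 over 4 probes and IRF7, the main inducer of interferon genes, 2.48 ± 1.02 over 5. IRF8, a factor needed for dendritic cell development, was 5.7-fold over Ig in its highest window of 4 probes. All 3 windows were centred inside the gene and all 3 genes were called, but 18.79% (SPIB), 22.51% (IRF7) and 22.13% (IRF8) of all genes had a window as high. TCF4, which encodes E2-2 itself, had 2.02 ± 1.43 over 6 probes centred 788 bp upstream and was called, although 33.80% of all genes had a window as high. ID2, an inhibitor of helix-loop-helix factors, had 3.05 ± 2.28 over 5 probes centred 425 bp upstream and was called, although 12.28% of all genes had a window as high. TLR7, the endosomal RNA receptor of pDCs, had 1.49 ± 1.39 over 3 probes, with E2-2 over input at -0.09 there, and was not called in any window. With normexp correction TCF4 (0.72) and IRF8 (0.91) were not called, and TLR7 was called with loess (1.33) and with E2-2 over input alone (1.83).

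Cell cycle genes and cytosolic ribosomal protein genes stood apart as well. Of 38 cell cycle genes 30 were called against 19.99 expected (14 to 26), with a median of 2.44 against 1.592 and a percentile of 99.97. The highest were CDKN2C, an inhibitor of CDK4 and CDK6 (5.53 ± 1.27 over 4 probes, in a window shared with FAF1), E2F2 (4.92 ± 2.30), the cyclin gene CCND3 (4.23 ± 0.41) and the replication licensing factor CDT1 (4.19 ± 1.34). E2F2 was not called with at least 5 probes (0.26) or with 300 bp windows (0.57). Of 50 ribosomal protein genes 34 were called against 22.1 expected (15 to 29), with a median of 2.02 against 1.28 and a percentile of 99.98, led by RPS19 (5.58 ± 3.76 over 3 probes), RPS24 (5.08 ± 0.53), RPS9 (3.90 ± 2.32) and RPS27 (3.72 ± 1.65, in a window shared with RAB13). RPS9 was not called at 3-fold, with at least 5 probes or with probes well above background (0.22). On chip 1 alone, 17 of 23 ribosomal genes were called against 10.42 expected (6 to 15). The percentile of the ribosomal list there was 94.55, so it did not stand apart. Nor did it in windows beyond 1 kb of a start site (95.07), or the cell cycle list in windows within 1 kb (97.39). Ig over input placed the cell cycle list at percentile 39.51 and the ribosomal list at 68.92. The highest windows lay within 1 kb of a start site for 76.0% of ribosomal protein genes, 41.9% of pDC genes and 23.7% of cell cycle genes, against 45.1% of all genes.

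The other 9 lists did not stand apart in E2-2 over Ig with the main setting. Several did under alternatives given below, and olfactory receptors kept this result under only 7 of 15. The TLR and interferon induction pathway had 23 of 38 genes called against 18.3 expected, at percentile 96.78. Its highest members were the kinase gene IKBKE (4.97, not called with at least 5 probes), TLR8 (4.50), TLR9 and UNC93B1, the last 2 of which were among 6 genes it shared with the pDC list; without these 6 it lay at 87.06. B cell genes had 24 of 35 called against 17.6 expected (12 to 23), at percentile 89.93. They included PRDM1, the plasma cell regulator (4.99), DNTT (4.75), the surrogate light chain gene IGLL1 (4.19) and BACH2 (3.96). Helix-loop-helix factors and Id proteins had 20 of 27 called against 15.6 expected, at percentile 86.12, with TCF12, a close relative of E2-2, at 5.07 ± 2.08 and MITF at 3.44 ± 2.32. TCF12 and MITF also held an Ig-enriched window, with lowest windows of -4.46 and -3.80. The list also holds genes that encode neither kind of protein, among them CBFA2T3 at 4.17 and RUNX1T1 at 3.35 ± 3.92 over 4 probes. RUNX1T1 held an Ig-enriched window too, with a lowest window of -4.04, and CBFA2T3 held none. In Ig over input alone this list lay at percentile 99.13. Haematopoietic transcription factors had 27 of 43 called against 25.1 expected, at percentile 55.28, with RUNX1 at 4.67, BCL11A at 3.93, IKZF1 at 3.39 and STAT5A at 3.29. The IKZF1 window was centred 93622 bp inside the gene.

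T and NK cell genes had 18 of 44 called against 22.3 expected (percentile 34.02), and called members included CD27 (4.16), ZAP70 (3.91) and RORA (3.61). Conventional dendritic cell and myeloid genes had 18 of 46 called against 23.4 expected (percentile 26.26), with the class II transactivator gene CIITA at 5.18, CX3CR1 at 4.06, SIRPA at 4.01 and LYZ at 3.68. Interferon-stimulated genes had 13 of 30 called against 13.1 expected (percentile 7.76, but from 3.22 to 97.37 across alternatives), and the RNA sensor gene IFIH1 reached 5.67, SAMD9L 3.39, ISG20 3.22 and MX1 3.14. Genes of liver, muscle, pancreas and neurons had 23 of 47 called against 26.4 expected (percentile 6.17), led by GFAP (4.73), MYH2 (4.16), MBP (3.91) and NPPA (3.90). The GFAP window was centred 10830 bp from the start, at a probe placed downstream of the gene. Olfactory receptors had 78 of 293 called against 117.8 expected (102 to 134) but a median at percentile 14.66. That percentile was 93.88 on chip 1 alone and 1.82 on chip 2 alone. The highest of them were OR5H1 (4.92), OR9Q2 (4.75), OR4D2 (4.41) and OR2T4 (4.05). With probes well above background, SIRPA, SAMD9L, OR9Q2 and OR4D2 were not called, the last at -0.74.

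The 12 regions with the highest E2-2 over Ig ranged from 5.97 to 7.03. Besides DNASE1L3 they included MALL (6.63 ± 0.43), the somatostatin receptor gene SSTR2 (6.52 ± 1.17), the Fc receptor-like gene FCRL2 (6.35 ± 0.95), TMEM184B (6.29 ± 1.26), the cystine transporter gene CTNS (6.18 ± 1.82), AMOT (6.16 ± 1.20), CEP97 (6.12 ± 1.40), the homeobox gene PBX3 (6.11 ± 1.08), SHQ1 (5.98 ± 2.34) and MCUB (5.97 ± 1.04). Each of these named regions rested on 3 or 4 probes, with Ig over input between -3.01 and -2.02. TMEM184B was not called with at least 5 probes (0.08) and PBX3 was not called with 300 bp windows (2.35). The lowest mirror regions reached like sizes, at BMP3 (-7.06 ± 0.39), SIDT2 (-6.78 ± 1.79) and RAB3IP (-6.76 ± 1.30).

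Over the whole set, 10417 regions were E2-2-enriched and 7514 were Ig-enriched by the mirrored thresholds, which is 72.1 Ig regions per 100 E2-2 regions. Of 17428 genes, 8594 (49.3%) had an E2-2-enriched window and 6317 (36.2%) an Ig-enriched one. Both kinds of window were found at 3054 genes, against 3115 expected if the calls were independent. On chip 1 the counts were 5403 and 4775 regions, and on chip 2 they were 5014 and 2739. When only the difference between antibodies was used, without a minimum over input, Ig regions outnumbered E2-2 regions at every threshold tried up to 103.97-fold. There were 7572 against 7118 at 4-fold and 762 against 617 at 16-fold. After both arrays of a design were scaled to one spread, the counts were 8941 and 8864. A simulated pair of unrelated arrays gave 9818 and 10530 regions. That pair was the Ig ratios set against their own shifted copy. It lacks the correlation and the difference in spread of the real arrays, so its counts are not a like background.

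**Figure D3:**
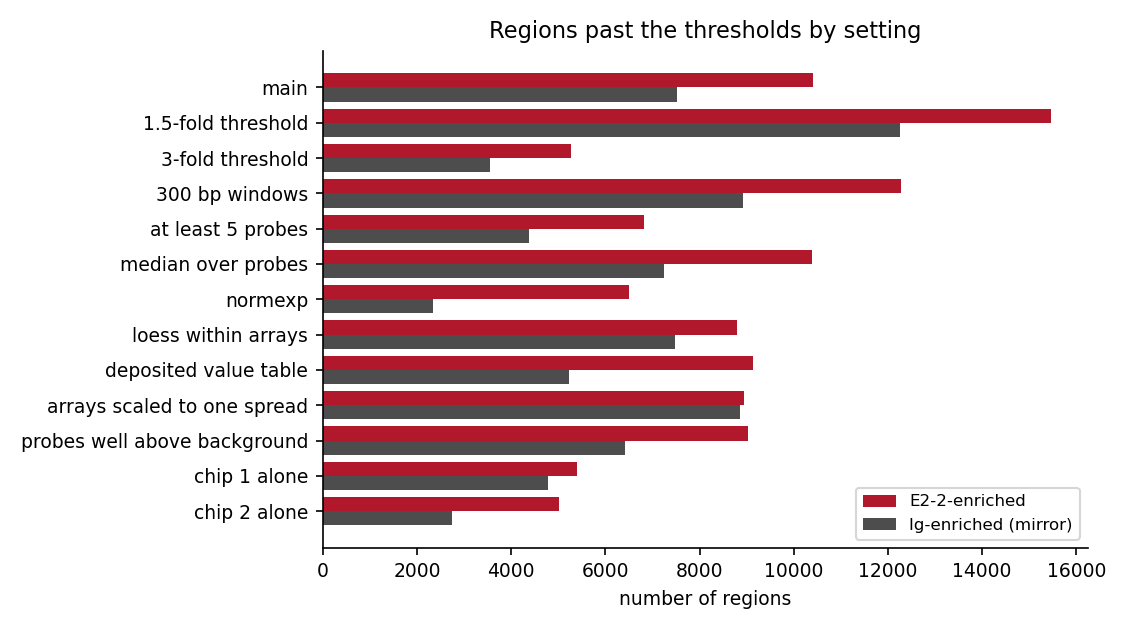
Number of regions past the thresholds (horizontal axis) that were E2-2-enriched (red) or, with the antibodies exchanged, Ig-enriched (grey), under each processing setting (vertical axis). With the main setting the bars are 10417 and 7514, and with arrays scaled to one spread they are 8941 and 8864.

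E2-2-enriched regions lay near start sites more often than windows in general. Of their highest windows, 4781 of 10417 (45.9%, 95% Wilson interval 44.9 to 46.9, counting error only) were within 1 kb of a start site. The share was 40.1% of all windows and 32.9% (31.8 to 34.0) of Ig-enriched regions. When regions were called anew from windows within 1 kb of a start site alone, there were 5703 E2-2 and 3029 Ig regions, and from windows beyond it 6311 and 5366. Both immunoprecipitates peaked at start sites. On average over probes within 500 bp, E2-2 over input was 0.48 and Ig over input 0.33, and beyond 3000 bp they were -0.57 and -0.35. With the median over probes the share of E2-2 regions near start sites was 41.3%, and with loess within arrays it was 36.9%, below the share of all windows.

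**Figure D4:**
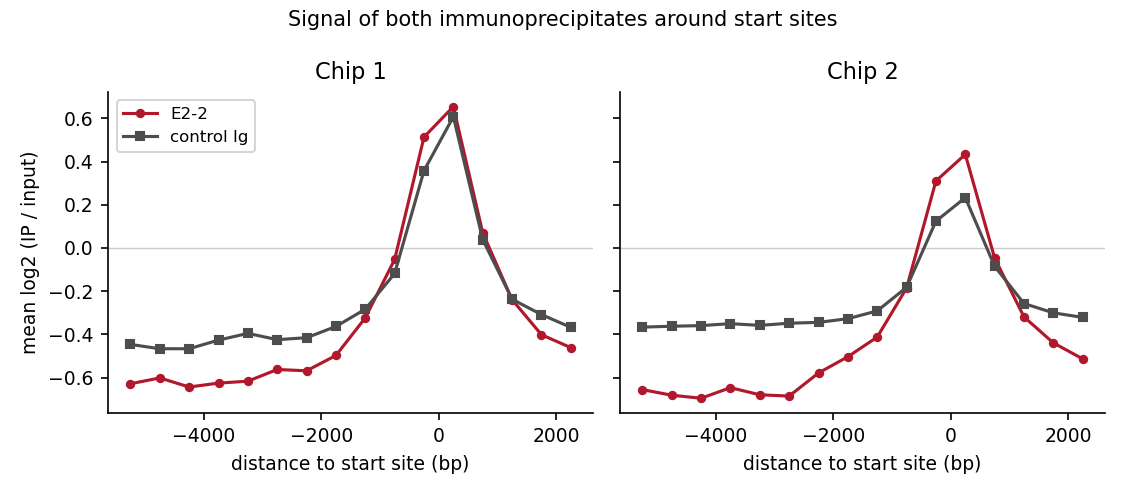
Mean log2 ratio of immunoprecipitate over input in 500 bp bins (vertical axis) against distance to the start site in bp (horizontal axis) for E2-2 (red) and control Ig (grey) on each of the 2 designs. Both curves peak at the start site, and E2-2 lies below Ig far upstream.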

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

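Alternatives with the mean over all windows and with windows within or beyond 1 kb of a start site, with shared promoters counted once or with pDC genes left out of the other lists, and most of those on the distance to start sites, were chosen after the data were seen. No paired analysis was possible because each antibody has 1 array per design. No threshold on E2-2 over Ig brought the mirror regions down to 5% of the E2-2 regions, so that alternative gave no value, and the GC correction and E-box search were not run. The pDC list stood apart under all 15 alternatives, at percentiles from 99.86 to 100. The cell cycle list did so under 14 of 15 (97.39 within 1 kb) and the ribosomal list under 13 of 15 (94.55 on chip 1 alone, with fewer genes, and 95.07 beyond 1 kb). Interferon-stimulated, myeloid, and T and NK cell genes stood apart under none of those run, but the interferon-stimulated list ranged from 3.22 with loess to 97.37 with 300 bp windows. Others came to stand apart on the high side: the TLR pathway with loess (97.93) and beyond 1 kb (99.69), B cell genes with the median over probes (99.98) and normexp (99.51), helix-loop-helix genes with probes well above background (97.79) and the mean over all windows (99.21), and haematopoietic factors with E2-2 over input alone (98.28). On the low side were liver, muscle, pancreas and neuron genes with the median over probes (1.6), normexp (2.46) and E2-2 over input (2.04). Olfactory receptors were there with at least 5 probes (1.03), on chip 2 alone (1.82), with the value table (2.24), within 1 kb (0.02), and at 0.00 with normexp, probes well above background, E2-2 over input and the mean over all windows, but at 93.88 on chip 1 alone and 47.69 after scaling. Counts of E2-2 regions, mirror regions and called genes were 5262, 3540 and 4787 at 3-fold, 5403, 4775 and 4327 on chip 1, and 5014, 2739 and 4267 on chip 2, the last 2 from fewer probes. E2-2 and mirror regions numbered 6817 and 4371 with at least 5 probes, and 6497 and 2333 with normexp. Mirror regions numbered 12246 at 1.5-fold, and Ig over input alone gave 13258. The E2-2 share of called regions was 58.1%, against 73.6% with normexp and 50.2% after scaling. The median gene's highest window was 1.504, against 0.757 with normexp and 1.098 with loess. The share of E2-2 regions near start sites was 55.9% over input alone, 55.8% with at least 5 probes, 50.2% with probes well above background, 49.2% with normexp, 48.7% with the value table, 41.3% with the median over probes and 36.9% with loess. The share of all windows near start sites was 45.9% with at least 5 probes, 47.5% with probes well above background and 40.1% under the other settings in that list. The share of E2-2 regions is thus to be set against a higher baseline with either filter. Of the regions called from Ig over input alone, 51.1% lay near start sites, against the 55.9% for E2-2 over input. Among 77 named genes, fewest calls were kept with at least 5 probes (61 of 75) and with probes well above background (67 of 76). DNASE1L3 turned to -0.54 with at least 5 probes, where its 3-probe window drops out, and OR4D2 to -0.74 with probes well above background. Apart from the fewer probes or genes named, the cause was not tested.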

Other observations

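The gene families below, the comparison with housekeeping genes, and the tests of Ig over input, of single designs, of dim probes and with weighted deciles of input signal were chosen after the result was seen, although the single designs and the filter on dim probes were planned as alternatives. In E2-2 over Ig, proteasome subunits had 27 of 38 genes called and lay at percentile 99.47, and mitochondrial ribosomal proteins had 43 of 75 called at percentile 98.56. Subunits of respiratory complex I (24 of 35, percentile 86.70) and spliceosome proteins (20 of 43, percentile 60.85) did not stand apart. The count of families that stood apart, 2 of 4, fell between the bounds set before their values were computed (at least 3 for a general enrichment of housekeeping promoters, at most 1 against it), so the comparison with housekeeping genes below replaced that test. Among tissue-restricted families, keratins had 15 of 50 called and lay at percentile 0.19, and MAGE antigens, germ cell genes, had 5 of 16 called at percentile 2.03. Beta-defensins (2 of 10, percentile 35.18) and taste receptors (7 of 19, percentile 46.62) did not stand apart. In Ig over input, keratins (percentile 0.05) and MAGE antigens (2.25) were low as well and taste receptors lay at 2.58, whereas proteasome genes lay at 57.47 and mitochondrial ribosomal proteins at 44.74.

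The pDC list stood apart in E2-2 over Ig. In Ig over input the list lay at percentile 20.2, so it was not high in the control as well. A property that raises both immunoprecipitates alike on the log2 scale cancels in E2-2 over Ig. The Ig percentile therefore decides nothing about such a property. A property that raises mainly the E2-2 immunoprecipitate is not excluded by it either. The ribosomal list, at 99.98 in E2-2 over Ig, lay at 68.92 in Ig over input. Neither design alone carried the high median of the list, as the lower of the 2 percentiles was 99.86. The count of called pDC genes lay above the range of random draws on chip 2 only. It was 27 of 35 there against 17.89 expected (12 to 23), and 18 of 27 on chip 1 against 15.69 expected (11 to 20). The cell cycle and ribosomal counts lay above their ranges on chip 1 only. They were 15 of 17 (5 to 13) and 17 of 23 (6 to 15) on chip 1, and 15 of 21 (6 to 15) and 17 of 27 (7 to 17) on chip 2. Signal at start sites was not the whole source of the high median of the pDC list, as windows beyond 1 kb gave percentile 99.99. One explanation stays open: the excess of pDC genes over matched genes, a median of 0.63, lay at percentile 84.23 of lists drawn from 241 housekeeping genes, whose median excess was 0.48. The list may therefore reflect enrichment of promoters active in CAL-1 in general, specific binding of E2-2 to pDC genes, which the antibody comparison was made to measure, or both.

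Many windows favoured Ig over E2-2. Dim probes, among them those lost in either immunoprecipitate, were not the whole source. With probes well above background, 19070 of 289663 windows were still Ig-enriched, against 22776 of 419311 without that filter. The 71.2 Ig regions per 100 E2-2 regions under that filter decide nothing, since dim probes can add regions in both directions. Partial loss stays open. Among probes well above background in both inputs, lost probes coincided between the antibodies up to 3.41 times as often as independent loss would give. This decides nothing, since weakly hybridising probes could fall near background on both arrays, which was not tested. Of the probes counted, 4.28% (chip 1) and 4.83% (chip 2) were lost with E2-2 alone. With probes shuffled within each design, which removes any likeness between neighbouring probes, 54.3% as many mirror windows were called (SD 0.43 over 20 shuffles), between the bounds of 50% and 90% set beforehand, so the part of noise independent between spots stays open. Uneven amplification of small amounts of DNA and binding to the control Ig were not tested.

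E2-2 over Ig was higher near start sites than far from them, by 0.367 on average over probes (within 500 bp against beyond 3000 bp). With loess within arrays the difference was 0.093, so a dependence of the ratio on the spot signal could account for most of it, although loess also removes true enrichment that brightens a spot. Within deciles of the input signal the difference was 0.201 (jackknife SE 0.017 over 23 chromosomes). This exceeded the bound set beforehand, 50% of the original difference, by 0.0174 (SE 0.0098), but with deciles weighted by their probes near start sites the difference was 0.179 (SE 0.016), within its error of the bound, so the input signal as its main source stays open. No biological explanation was tested for it.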
